A study of Sus scrofa with 3 samples.

How the data were processed

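Total RNA from the liver of male pigs at postnatal day 90 was extracted with TRIzol, and small RNA of 14 to 40 nucleotides was selected on a gel, ligated to adaptors, amplified and sequenced as single-end reads of 50 bases on an Illumina HiSeq, per the labels' protocols. The labels give 1 library for each of 3 breeds and do not say whether animals were pooled, so every comparison is between 1 library and another. The genome build was Sscrofa 10.2, per the submitters' processing notes. The aligner, the counting tool and the miRNA annotation are not given in the sources used here.

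The deposited files give, per the file headers, a read count for each pair of mature miRNA and precursor. They hold the same 486 rows with 411 mature names and 382 precursors. These are expected counts as deposited: 75.7% of the rows in the Enshi black, 78.8% in the Large White and 76.5% in the wild boar library were exact whole numbers, and the others held fractions where reads match several precursors or names. The deposited files also give RPM, which is the read count divided by the sum of all rows of a library, times 1000000. The RPM values were not used for any comparison, since counts were at hand. Whole-number counts had been assumed when the comparisons were planned, so the expected counts were rounded to whole numbers after summing.

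Counts of a mature miRNA were summed over its precursors. Rows of 6 names repeated the reads of another name and were left out (miR-218-5p and miR-218b for miR-218, miR-339-5p for miR-339, miR-490-3p for miR-490, and miR-9-1 and miR-9-2 for miR-9). miR-129a-5p and miR-129b had equal counts in all libraries but on different precursors, so both were kept, below the expression minimum. This left 405 miRNAs, of which 317 had a count, and totals of 7730934, 7343033 and 7824836 for the Enshi black, Large White and wild boar libraries. Comparisons used the 208 miRNAs with a mean CPM of at least 10 over the 3 libraries. Of these, 65 hold reads shared with another name, seen as a sum more than 0.05 from a whole number, as in the let-7 family, the pair miR-192 and miR-215, or the 3p arms of miR-199a and miR-199b, and their values depend on how the authors' counting divided those reads.

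CPM were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.20 for the Enshi black, 0.772 for the Large White and 1.08 for the wild boar library. TMM assumes that most miRNAs do not differ between libraries. A few miRNAs take most reads here, so the choice of scaling moves all ratios of a pair together. The ratio of 2 libraries was given an exact conditional-binomial 95% interval. A miRNA counted as higher or lower where it was at least 2-fold apart with an interval that left out 1. No p-value was computed, since 1 library per breed gives no estimate of the spread between animals. Reads carry no molecular identifiers, so intervals and the floor of 3 counts for a count of 0 cover counting error only. As a check of the computation, counts were simulated from the Large White profile at each library's total, with counting noise only. With 198 miRNAs tested for wild boar over Large White, the rule picked 18 of 18 miRNAs simulated at 4-fold, 0 of 19 at 1.5-fold and 0 of 161 unchanged ones. The simulation held no spread between animals, so it does not show how the rule performs on the real libraries.

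The 14 miRNA groups, the rule for the miRNAs named and the alternatives were fixed before the data were examined. An entry without an arm took its more abundant arm. For each group, the median log2 ratio of the members above the minimum was set against 10000 random lists of the same size, each member drawn from the 20 miRNAs nearest in mean expression. The percentile describes these libraries and is no test. A change of scaling moves a group and its random lists together, so it cannot change the percentile. Random members were drawn singly, while some groups hold neighbours in the genome. Neighbours within 10 kb were closer than random pairs (0.37 against 0.64 in Enshi black over Large White), so such groups can reach extreme percentiles more easily. Named miRNAs were the 12 with the highest and the 12 with the lowest ratio of each pair among those past the rule, first at a mean CPM of at least 100 and then from 10 to 100. The 10 most abundant miRNAs of each library, up to 4 members per group in order of mean CPM, and the 5 precursors with the widest range of 5p share were also named. Further group members past the rule are named where a count of 5 or fewer is given, chosen after their values were seen. Arm shares were computed for precursors with at least 100 reads over both arms in each library, with exact Clopper-Pearson intervals.

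Alternatives were CPM of the library total, CPM without miR-122, DESeq2 1.42.0 size factors, no expression filter, a minimum of 100 CPM, a 4-fold threshold, libraries thinned to the smallest total, a detection minimum of 1 count and arm shares with at least 1000 reads. Leaving out miRNAs with shared reads was added after seeing the data. Neighbouring miRNAs were found by name in RefSeq genes of Sscrofa 11.1, where 315 of the 382 precursors matched. That assembly differs from the authors' build, so no coordinates are given. Base composition of the mature miRNAs was not analysed here. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.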

Results

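Small RNA was sequenced from the liver of male pigs at postnatal day 90, with 1 library for each of 3 breeds. The breeds were the Enshi black pig, a Chinese domestic breed, the Large White pig, a European commercial breed, and the Chinese wild boar. The comparisons between them address how the liver microRNA (miRNA) profile differs between breeds at the same age. The deposited read counts summed to 7739853 in the Enshi black library, 7350179 in the Large White library and 7837309 in the wild boar library. With 1 library per breed, no difference below has a replicate check, and all intervals are exact 95% intervals that cover counting error only. Differences between libraries therefore include any difference between individual animals.

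The liver-specific miR-122 was the most abundant miRNA in each library. It took 34.2% of the miRNA reads in the Enshi black library (exact Clopper-Pearson interval 34.17 to 34.24), 41.4% in the Large White library (41.37 to 41.44) and 39.5% in the wild boar library (39.46 to 39.53). The 10 most abundant miRNAs together held 66.5%, 76.1% and 70.1% of the reads in the same order. Members of the top 10 in all 3 libraries were miR-122, miR-101, miR-192, miR-194a, miR-21, miR-26a, miR-29a and let-7a. miR-192 and miR-194a are processed from shared transcripts and are abundant in liver, and miR-21 is a widely expressed miRNA linked to growth and fibrosis. The Enshi black top 10 also held miR-143-3p and miR-199a-5p, which are typical of smooth muscle and fibroblasts, at 22547 and 16638 CPM (counts per 1000000 of the library's total after trimmed mean of M-values, TMM, scaling). The other two libraries held miR-148a-3p and let-7c in their place. At least 10 counts were found for 270 miRNAs in the Enshi black, 262 in the Large White and 272 in the wild boar library, and a count of 0 allowed up to 0.323, 0.529 and 0.356 CPM on that scale.

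Compared with the Large White library and after TMM scaling, the Enshi black library had less of several of the most abundant liver miRNAs and more of a small set of scarcer miRNAs. On library totals, most miRNAs past 2-fold were instead higher in the Enshi black library, 57 against 6. Those included the abundant miR-126-3p, miR-199a-5p and miR-143-3p. miR-101 stood 3.19-fold higher in the Large White library (interval 3.18 to 3.20) and miR-192 2.34-fold higher (2.33 to 2.35). miR-22-3p, which is linked to glucose metabolism, was 3.09-fold higher in the Large White library (3.05 to 3.12), and its partner arm miR-22-5p 2.01-fold higher (1.87 to 2.16). Also named on the Large White side were miR-1285 at 3.84-fold, miR-874 at 3.19-fold, miR-215 at 2.75-fold, the red cell miR-144 at 2.31-fold, miR-32 at 2.30-fold, miR-29b at 2.23-fold, the leucocyte miR-142-3p at 2.09-fold and miR-7 at 2.02-fold. On the Enshi black side, miR-15b was 2.42-fold higher (2.30 to 2.54), miR-146b, which is induced by inflammatory signalling, 2.47-fold (2.19 to 2.78) and miR-10b 2.12-fold (1.85 to 2.44). miR-758 was 6.48-fold higher (3.99 to 11.2) on 191 against 18 reads, miR-370 2.75-fold (1.78 to 4.38) and miR-490 2.12-fold (1.45 to 3.16).

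Among the miRNA groups fixed beforehand, the liver-enriched group was shifted towards the Large White library, with a median log2 ratio of Enshi black over Large White of −0.91. That was the 0.015 percentile of 10000 random lists drawn from the miRNAs nearest in expression. No other miRNA was as abundant as miR-122, so it had no close match. Those lists also did not keep genomic neighbours such as miR-192 and miR-194a together. The median was −0.27 on library totals, where the percentile cannot change because 1 factor moves all ratios of a pair. It was −0.67 among the 9 members of at least 100 mean CPM (0.42 percentile). Of its 11 members, miR-101, miR-192 and miR-885-5p were at least 2-fold lower in the Enshi black library and none was 2-fold higher. On library totals miR-192 and miR-885-5p had log2 ratios of −0.59 and −0.85, under 2-fold. miR-122 and miR-194a had log2 ratios of −0.91 and −0.93. The endothelial group had a median of 0.59, which none of its 10000 random lists exceeded. Those lists were drawn without keeping genomic neighbours such as miR-23a and miR-27a together. 1 of the group's 11 members, miR-10b, was at least 2-fold higher, while the endothelial miR-126-3p had a log2 ratio of 0.68 and miR-125b one of −0.28. On library totals the endothelial median was 1.23. There miR-10a-5p, miR-27a, miR-126-3p, miR-100 and miR-23a were also past 2-fold, at 1.43, 1.37, 1.31, 1.25 and 1.23. The 6 miRNAs of the imprinted DLK1-DIO3 cluster above the expression minimum had a median of 0.79 (99.9 percentile), with miR-758 and miR-370 at least 2-fold higher, and miR-136 at −0.63. Random lists for this cluster were likewise drawn without keeping neighbours together. On library totals miR-127, miR-299 and miR-369 were also past 2-fold, at 1.51, 1.35 and 1.01, and miR-136 had 0.01. The p53 and stress responsive group had a median of −0.48 (4.42 percentile, and 6.30 among miRNAs of at least 100 mean CPM), with miR-192 and miR-215 lower. That median was 0.16 when counts were scaled to the library total. On that scale miR-192 and miR-215 were under 2-fold, at −0.59 and −0.82, and miR-210 of the p53 group was past 2-fold higher at 1.21. The 3 striated muscle miRNAs had a median of −0.75 (4.7 percentile), which was −0.12 on library totals, with no member past 2-fold.

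The other groups lay nearer the middle of their random lists in this pair. The lipid and cholesterol group had a median of 0.14 over 18 members, which turned to −0.04 among those of at least 100 mean CPM, with miR-758 and miR-370 higher and miR-144 lower, while its most abundant members miR-26a, miR-21, miR-29a and miR-143-3p had log2 ratios of −0.22, −0.48, −0.09 and 0.43. The glucose and insulin group (13 members, 2 lower) had a median of −0.09, which was 0.55 on library totals. There its 2 lower members, miR-22-3p and miR-29b, were under 2-fold at −0.99 and −0.52. Its members miR-27a, miR-126-3p, miR-130a and miR-143-3p were then past 2-fold higher, at 1.37, 1.31, 1.11 and 1.07. The fibrosis and stellate cell group (13 members, 1 higher and 1 lower) had 0.18, the miR-17-92 group (9 members) 0.16 and the leucocyte group (11 members, 1 higher and 1 lower) 0.00. On library totals these medians were 0.82, 0.80 and 0.64, and that of the lipid group 0.78. Also 2-fold higher there were miR-30c-5p, miR-27a and miR-143-3p (lipid), miR-222, miR-199a-5p and miR-143-3p (fibrosis), and miR-363, miR-20b and miR-17-5p (miR-17-92). The same held for miR-139-5p, miR-181b and miR-181a (leucocyte), while miR-29b and miR-142-3p were then under 2-fold at −0.52 and −0.43. The let-7 family (8 members) had −0.37, which became 0.27 on library totals. The erythroid group (7 members, 1 lower) had −0.15 and the neural and endocrine group (3 members, 1 lower) −0.06, and these became 0.48 and 0.58 on library totals, with the neural median at 0.02 under DESeq2 size factors. On those totals the lower members miR-144 and miR-7 were under 2-fold, at −0.57 and −0.37. The erythroid miR-363 and miR-16 were then past 2-fold higher, at 1.36 and 1.21. Of the biliary and epithelial group only miR-429 passed the expression minimum, with a log2 ratio of 0.39, which was 1.03 on library totals.

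In all, 6 of 208 miRNAs were at least 2-fold higher and 21 at least 2-fold lower in the Enshi black than in the Large White library after TMM scaling. Of the 6, miR-15b, miR-146b and miR-10b hold reads shared with another name, and 3 were higher when such miRNAs were left out, an alternative chosen after seeing the data. TMM moved every log2 ratio of this pair by −0.64, and on library totals the median miRNA had a log2 ratio of 0.60. The split was then 57 higher and 6 lower, and 37 higher and 8 lower on totals without miR-122. Named miRNAs were at least 2-fold apart and the shift in scaling was smaller, so none could change its direction. On library totals 9 of the 12 named on the Large White side were under 2-fold.

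**Figure D1:**
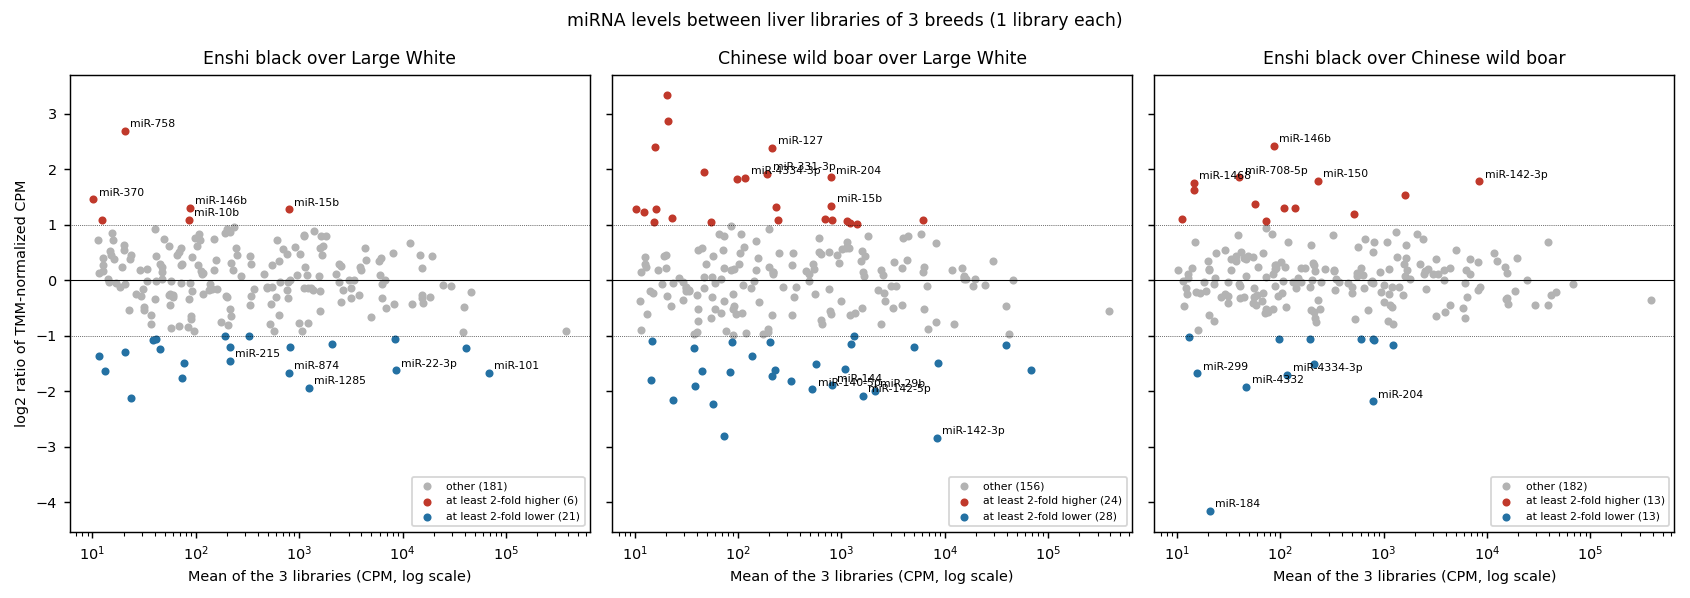
The log2 ratio of TMM-normalized CPM (vertical axis) is plotted against the mean CPM of the 3 libraries (horizontal log axis) for each of 208 miRNAs in each pair of breeds. Red and blue points mark miRNAs at least 2-fold higher or lower with a counting interval that leaves out 1, and these number 6 and 21, 24 and 28, and 13 and 13 from left to right.

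The wild boar and Large White libraries were furthest apart, with an SD of the log2 ratios over miRNAs of 0.96 against 0.69 and 0.70 in the other pairs. In the wild boar library, 4 of 11 leucocyte group miRNAs were lower after TMM scaling. On library totals miR-139-5p and miR-181a of that group were at least 2-fold higher in the wild boar library. Of the 6 miRNAs of the imprinted DLK1-DIO3 cluster above the expression minimum, 5 were higher there. miR-142-3p, a miRNA of blood-forming cells, stood at 2346 CPM in the wild boar and 16873 CPM in the Large White library, which is 7.19-fold higher in the latter (7.08 to 7.30). Its other arm miR-142-5p was 4.23-fold higher in the Large White library (4.10 to 4.37), and the lymphocyte miR-150 3.06-fold (2.80 to 3.34). The cluster miRNA miR-127 was 5.22-fold higher in the wild boar library (4.71 to 5.79). miR-204 was 3.61-fold higher (3.46 to 3.77), miR-331-3p 3.78-fold (3.42 to 4.18) and miR-4334-3p 3.59-fold (3.20 to 4.05).

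The other named miRNAs on the wild boar side were miR-15b at 2.52-fold, miR-505 at 2.50-fold, miR-148b-3p at 2.15-fold, miR-542-5p at 2.13-fold, miR-365-3p at 2.12-fold, miR-30d at 2.11-fold, miR-30c-5p at 2.08-fold and miR-339 at 2.05-fold. miR-30c is known to lower lipoprotein secretion through microsomal triglyceride transfer protein. On the Large White side, miR-29b, a repressor of collagen genes, was 3.99-fold higher (3.89 to 4.09) and miR-140-5p 3.91-fold (3.71 to 4.13). miR-144 was 3.72-fold higher there, miR-7 3.52-fold, miR-215 3.32-fold, miR-101 3.06-fold, miR-19a 3.03-fold, miR-542-3p 2.86-fold and miR-22-3p 2.83-fold.

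The DLK1-DIO3 group stood furthest from its random lists in this pair, with a median log2 ratio of wild boar over Large White of 1.83 (99.97 percentile). The group comes from 1 cluster, while members of its random lists were drawn singly, so an extreme percentile is reached more easily. Of its 6 members above the expression minimum, 5 were at least 2-fold higher. They were miR-127, miR-758 (3.33 on the log2 scale), miR-299 (2.39), miR-369 (1.28) and miR-370 (1.28). The remaining member, miR-136, had a log2 ratio of −0.97. miR-758 and miR-370 rest on 18 and 26 reads in the Large White library, which is 3.17 and 4.58 CPM after TMM. They passed the minimum of 10 mean CPM through the other libraries. Of 17 cluster members named in the counts, 6 passed that minimum. In the leucocyte group, 4 of 11 members were at least 2-fold lower, namely miR-142-3p, miR-150, miR-146a-5p (−1.36) and miR-146b (−1.12). On library totals miR-146a-5p and miR-146b had log2 ratios of −0.88 and −0.64, under 2-fold. The group's median was only −0.20 (20 percentile), and miR-139-5p, miR-181a and miR-424-5p had log2 ratios of 0.91, 0.67 and −0.11. On library totals the median was 0.28, and miR-139-5p and miR-181a were past 2-fold higher in the wild boar library, at 1.39 and 1.15. The erythroid group had a median of −0.59 (2.43 percentile), with miR-144 the 1 member of 7 past 2-fold, while miR-451 and miR-16 had log2 ratios of −0.51 and 0.36. On library totals the erythroid median was −0.11, and miR-451 and miR-16 had −0.03 and 0.84.

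The 3 striated muscle miRNAs had a median of −0.97 (2.24 percentile), with miR-1 past 2-fold at −2.23, miR-499-5p at −0.97 and miR-133a-3p at −0.46. On library totals the muscle median was −0.49 and miR-133a-3p had 0.02 (−0.30 to 0.34). The endothelial group had a median of 0.43 (96.1 percentile, and 90.8 at a mean CPM of at least 100), with none of its 11 members past 2-fold. On library totals its median was 0.91, and miR-10b, miR-27b-3p and miR-23b were past 2-fold at 1.46, 1.28 and 1.17. The liver-enriched group had a median of −0.55 (7.26 percentile), with miR-101 and miR-30e-5p lower, miR-365-3p higher, and miR-122 at −0.55. On library totals that median and miR-122 were both −0.07, and miR-455-3p passed 2-fold at 1.08. On library totals miR-30e-5p, miR-21 and miR-20b of this and the following groups had log2 ratios of −0.73, −0.69 and −0.61, under 2-fold. The lipid group had a median of 0.18, with miR-30c-5p, miR-758 and miR-370 higher and miR-21 and miR-144 lower among 18 members. The glucose group had a median of 0.02, with miR-22-3p and miR-29b lower, while miR-26a, miR-29a and miR-126-3p had log2 ratios of 0.00, −0.08 and 0.19. The fibrosis group had a median of 0.10 with miR-222 higher and miR-21 and miR-29b lower, while miR-199a-5p had a log2 ratio of 0.22. The miR-17-92 group had a median of −0.49, which was −0.01 on library totals, with miR-19a and miR-20b lower, and miR-92a at 0.84. The p53 group had a median of −0.47, which was 0.01 on library totals, with miR-21 and miR-215 lower. The let-7 family had a median of −0.24 and no member past 2-fold. On library totals its median was 0.24 and let-7e was past 2-fold higher at 1.05. The neural group had a median of 0.42 with miR-7 lower, and miR-429 of the biliary group had a log2 ratio of 0.29. The lipid, glucose, fibrosis and neural medians were 0.66, 0.50, 0.58 and 0.90 on library totals. Also past 2-fold higher there were miR-27b-3p and miR-107 of the lipid group, at 1.28 and 1.07. The same held for miR-107 in the glucose and p53 groups, and for miR-10b and miR-221-3p in the fibrosis group (1.46 and 1.24). miR-92a and miR-9 then had 1.32 and 1.02.

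Of the 208 miRNAs, 24 were at least 2-fold higher and 28 at least 2-fold lower in the wild boar than in the Large White library. TMM moved the log2 ratios by −0.48 and the median on library totals was 0.46. The split was 45 higher and 19 lower on library totals, and 43 and 19 without miR-122. The 12 miRNAs named on the Large White side stayed past 2-fold under each scaling. Each alternative raised the ratios of wild boar over Large White, so the 12 on the wild boar side could not fall under 2-fold. Base composition, which can bias library preparation, was not analysed here for any of the 208 miRNAs.

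**Figure D2:**
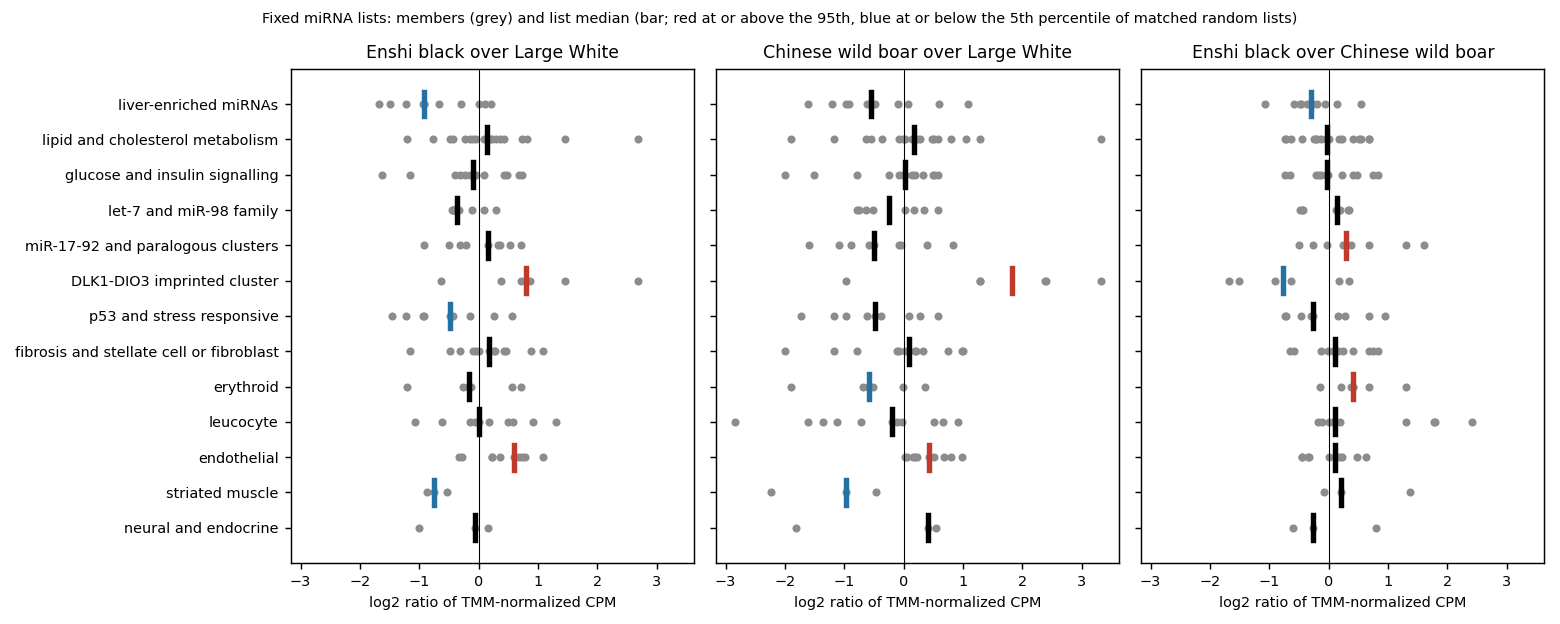
The log2 ratio of TMM-normalized CPM (horizontal axis) is shown for the members (grey points) and the median (bar) of 13 miRNA groups in each pair of breeds. Bars are red at or above the 95 percentile and blue at or below the 5 percentile of matched random lists. The DLK1-DIO3 median is 1.83 in wild boar over Large White, and the liver-enriched median is −0.91 in Enshi black over Large White.

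Compared with the wild boar library, the Enshi black library had more of 4 of the 11 leucocyte group miRNAs and of miR-142-5p, while the group's median log2 ratio was 0.11. miR-146b was 5.35-fold higher (4.66 to 6.16), miR-150 3.45-fold (3.19 to 3.74), miR-142-3p 3.43-fold (3.38 to 3.49), miR-142-5p 2.88-fold (2.79 to 2.97) and miR-146a-5p 2.46-fold (2.23 to 2.71). Also higher were miR-708-5p at 3.62-fold, miR-1468 at 3.38-fold, miR-20b at 3.07-fold, the muscle miR-1 at 2.58-fold, miR-363 at 2.48-fold, miR-140-5p at 2.27-fold and miR-628 at 2.14-fold. On the wild boar side, miR-184 was 17.8-fold higher (12.01 to 27.6) on 421 against 26 reads, miR-204 4.54-fold (4.37 to 4.73), miR-4332 3.79-fold (3.25 to 4.43) and miR-4334-3p 3.27-fold (2.98 to 3.59). The cluster miRNAs miR-299 and miR-127 were 3.20-fold and 2.85-fold higher in the wild boar library. Also named on that side were miR-339 at 2.26-fold, miR-365-3p at 2.11-fold, miR-874 at 2.10-fold, miR-374b-5p at 2.10-fold, miR-497 at 2.09-fold and miR-331-3p at 2.09-fold.

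The DLK1-DIO3 group had a median log2 ratio of Enshi black over wild boar of −0.77 (0.445 percentile), with 2 of 6 members past 2-fold and miR-136 at 0.34. Members of its random lists were again drawn singly. The erythroid group had a median of 0.41 (98.7 percentile), with miR-363 higher, and miR-144 and miR-451 at 0.69 and 0.38. The miR-17-92 group had a median of 0.29 (96.5 percentile, and 94.97 at a mean CPM of at least 100), with miR-363 and miR-20b the 2 of 9 members past 2-fold and miR-19b at 0.37. The liver-enriched group had a median of −0.29 (2.91 percentile, and 5.69 at a mean CPM of at least 100), with miR-365-3p lower and miR-122 at −0.36. In the leucocyte group, 4 of 11 members were higher around a median of 0.11 (65 percentile), while miR-155-5p and miR-342 had log2 ratios of 0.09 and −0.12. The striated muscle group had a median of 0.21 with miR-1 higher.

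After TMM no member of the remaining groups passed 2-fold between these libraries, while on library totals miR-210 of the p53 group had 1.10. Their medians were −0.03 for the lipid group, −0.03 for the glucose group, 0.15 for let-7, −0.26 for p53, 0.11 for fibrosis, 0.11 for endothelial and −0.25 for neural miRNAs, and the lipid and glucose medians were 0.13 on library totals. miR-429 had a log2 ratio of 0.11. In total 13 of 208 miRNAs were at least 2-fold higher and 13 at least 2-fold lower in the Enshi black library. The split was 15 and 7 on library totals, where TMM had moved the log2 ratios by −0.16 and the median was 0.15. On those totals, 5 of the 12 miRNAs named on the wild boar side were under 2-fold.

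The share of reads from each arm of a precursor differed between the libraries by at least 10 percentage points for 9 of 57 precursors, and for 3 of the 33 with at least 1000 reads over both arms in each library. miR-542, from an X-linked miRNA cluster, gave 49.0% 5p reads in the wild boar library (exact Clopper-Pearson interval 47.7 to 50.3), 30.8% in the Enshi black (29.7 to 31.9) and 13.6% in the Large White library (12.8 to 14.5). miR-455 gave 31.2%, 33.2% and 18.6% 5p reads in the Enshi black, Large White and wild boar libraries, and miR-361 gave 66.6%, 56.3% and 68.9%. miR-296 gave 23.9%, 18.1% and 29.8% in the same order. miR-374b, part of whose reads also match another name, gave 93.8%, 83.3% and 98.7%. All 57 precursors had at least 100 reads over both arms in each library. Counting intervals of some pair of libraries were apart for 34 of them, including the 9, and the median range was 3.56 points. These shares compare reads within a library and need no scaling between libraries.

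**Figure D3:**
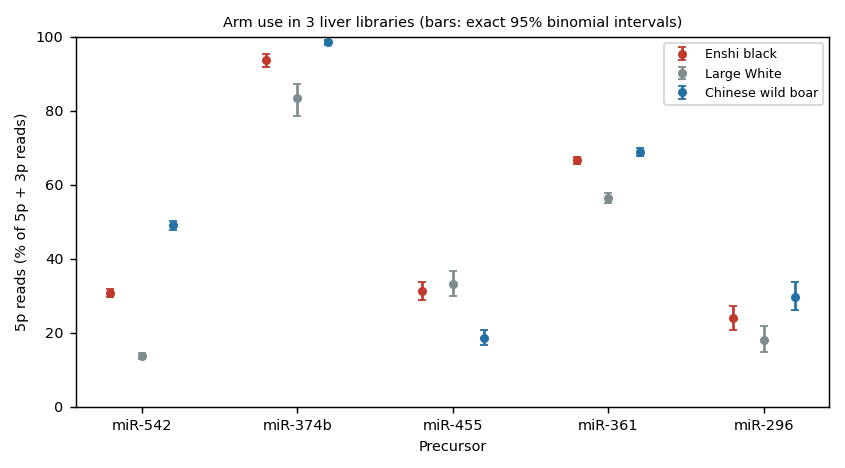
The share of 5p reads among all 5p and 3p reads of a precursor (vertical axis, percent) is plotted for the 5 precursors with the widest range, 1 point per library with its exact 95% binomial interval. For miR-542 the share is 13.6% in the Large White, 30.8% in the Enshi black and 49.0% in the wild boar library.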

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

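On library totals, the Enshi black to Large White counts were 57 higher and 6 lower and the wild boar to Large White count 45 higher, and Enshi black to wild boar had 7 lower. Without miR-122 in the total, the counts were 37 and 8 for the first pair and 43 higher for the second. These shifts follow from the alternative's construction, since 1 factor moves all ratios of a pair. The median of the p53 group in Enshi black over Large White reversed to 0.16 on library totals. DESeq2 size factors kept all 6 counts within 1.5 times. With no expression filter the counts higher and lower were 13 and 39, 38 and 47, and 21 and 29, for the 3 pairs in the order of the report. At a mean CPM of at least 100 they were 1 and 12, 13 and 18, and 6 and 8. At 4-fold they were 1 and 1, 4 and 5, and 1 and 2. These follow from more or fewer miRNAs passing. Without miRNAs that share reads, an alternative chosen after seeing the data, 3 were higher in Enshi black than Large White and the other counts stayed within 1.5 times. Without miR-122, the 10 next miRNAs held 52.0%, 61.5% and 53.7% of the remaining reads in the Enshi black, Large White and wild boar libraries. Group medians outside the 5 to 95 percentile range numbered 13. At a mean CPM of at least 100, the 5 of the DLK1-DIO3 and striated muscle groups had under 3 members and were not computed. Of the other 8, 4 stayed outside. Precursors with a 10-point range of 5p share numbered 3 of 33 with at least 1000 reads. Numbers of detected miRNAs stayed within 1.5 times, at 311, 304 and 307 with at least 1 count and 270, 262 and 271 after thinning. No paired analysis was possible because each breed has 1 library. Depth limits the scarce miRNAs, since 3 counts correspond to 0.323, 0.529 and 0.356 CPM in the Enshi black, Large White and wild boar libraries. The spread between animals was not measured.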

Other observations

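miR-204 and miR-184 were higher in the wild boar library than in both others. miR-204 reached 1516 CPM there, against 334 in the Enshi black and 420 in the Large White library, and miR-184 reached 49.9 CPM against 2.80 and 6.88. miR-184 and miR-204 are both known from eye and other epithelia, and neither sits in a group fixed beforehand. miR-124a, a neuronal miRNA, had 81 reads in the wild boar library, 1 in the Enshi black and 0 in the Large White library. In the Large White library miR-153 had 83 reads, against 2 and 10 in the Enshi black and wild boar libraries. miR-124a and miR-153 lie below the expression minimum and were picked after their values were seen.

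In 3 miRNA families, picked after their values were seen, members differed in wild boar over Large White. Here miR-30d and miR-30c-5p had log2 ratios of 1.08 and 1.06, whereas miR-30e-5p had −1.21, and these directions held on library totals. miR-29b and miR-29c had −2.00 and −0.78, with miR-29a at −0.08, whose sign turned on library totals. The closely related miR-15b and miR-15a had 1.33 and −0.60. On library totals miR-29c and miR-15a had only −0.30 and −0.12. miR-15b, miR-29b and at least 1 arm of miR-30e hold reads shared with another name. Their ratios depend on how those reads were divided.

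The tests below were all chosen after the results they bear on had been seen. In wild boar over Large White, miR-142-3p, miR-142-5p, miR-150, miR-146a-5p and miR-146b were all lower, with a median log2 ratio of −1.61. The choice of TMM over library totals as the whole cause is argued against for miR-150 and for miR-142-3p and miR-142-5p, arms of 1 precursor. Their highest upper 95% limit without TMM was −1.01. That explanation stays open for miR-146a-5p and miR-146b, which were then under 2-fold at −0.88 and −0.64 with a highest upper limit of −0.39. These miRNAs were split in this way after the values were seen. Removing TMM moves all ratios of the pair together, so other errors of scaling were not tested. Less blood left in the wild boar tissue stays open: the red cell miRNAs miR-451, miR-486 and miR-144 had log2 ratios of −0.51, −0.01 and −1.89 and a median of −0.51, so 1 of 3 fell as far. Without TMM these red cell miRNAs had −0.03, 0.47 and −1.41. Fewer leucocytes in the wild boar tissue also stays open, because the fixed leucocyte group, part of which is expressed in other liver cells, had a median at the 20.01 percentile only. Breed and the individual animal may each contribute, and 1 library per breed leaves them untested.

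The DLK1-DIO3 cluster was higher in the wild boar than in the Large White library, and of 15 cluster members with any count 10 had an interval above 1 and 1 below after TMM. Muscle carried over into the wild boar sample is not excluded: after TMM the muscle miRNAs miR-1, miR-499-5p and miR-133a-3p were all lower there, with a highest upper 95% limit of −0.14, but without TMM only miR-1 and miR-499-5p stayed lower, at −1.75 and −0.49, while miR-133a-3p had 0.02 and an upper limit of 0.34. Nerve tissue carried over into the wild boar sample stays open: after TMM, of 9 neural and endocrine miRNAs with a count, miR-124a and miR-9 (2 in number) had an interval above 1, and 3, among them miR-7 and miR-137, had one below 1. TMM had moved these log2 ratios by −0.48. Without it the intervals of miR-138 and miR-132 also lay above 1. That of miR-138 was then 0.44 to 1.37 on the log2 scale, and that of miR-132 was −0.004 to 1.43 after TMM. Without TMM the intervals of miR-7 and miR-137 stayed below 1. That of miR-216, with an upper limit of −0.07 after TMM, did not. A breed difference in imprinted expression may remain as a hypothesis that these libraries cannot separate from the individual animal.

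Arms of 1 precursor and neighbours in a cluster differed in wild boar over Large White, as with miR-542-5p and miR-542-3p (1.09 and −1.52), miR-140-5p and miR-140-3p (−1.97 and −0.44), miR-127 and miR-136 (2.38 and −0.97) and miR-17-5p and miR-19a (0.40 and −1.60). Of 38 precursors, 6 had arms at least 2-fold apart. Arms of a precursor were closer than pairs matched at random on expression, with a median difference of 0.42 against 0.86, and neighbours within 10 kb differed by 0.50 against 0.88. Base composition of the miRNAs, which can bias ligation and amplification, stays open here and for every other ratio between libraries. That includes the ratios of the leucocyte and DLK1-DIO3 miRNAs, since no mature sequences of the compared 208 were analysed. Processing, RNA decay and library preparation may each act on single arms, and no biological explanation was tested.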
